A study of Equus caballus with 9 samples.

How the data were processed

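Gene expression was measured by RNA sequencing in 9 cultures of horse (Equus caballus) tenocytes, the fibroblast-like cells of tendon. Per the labels, 3 lines were adult tenocytes from horses aged 2 to 6 years, 3 were fetal tenocytes taken at gestation days 319, 320 and 321, and 3 were tenocytes derived from embryonic stem cells (ESCs). The adult and fetal lines, called primary here, grew in high-glucose medium with 10% serum. The ESC lines were first kept on inactivated mouse feeder cells, then left without feeders or leukaemia inhibitory factor in a medium with 15% serum and 20 ng/ml of TGF-β3, a growth factor, for 14 days. Passage numbers were 18 to 22 in the ESC-derived lines and 3 to 7 in the primary lines. Passage, medium, serum, TGF-β3 and earlier culture on mouse feeder cells therefore changed together with the ESC-derived group. Per the labels, libraries came from a stranded mRNA kit and were read as pairs of 100 bases.

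The deposited table holds estimated counts per gene, which need not be whole. Per the submitters' processing notes, FastQC, Salmon and R 3.5.2 were used. The Salmon version and settings, the genome build, the annotation and the step from transcripts to genes are not given in the sources used here. Salmon divides reads that match several transcripts, so a gene with a near-identical copy can hold a fractional count. Of the 21689 gene identifiers, 4042 had a fractional value in at least 1 library and 4049 had a total of 0. Library totals ran from 20166692 to 23767643 counts. Intervals and lower bounds on folds used counts summed over the 3 libraries of a group. They cover counting error only and leave out variation between lines. Reads copied by PCR without molecular identifiers are not independent molecules, so the counting error itself may be larger.

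Counts were rounded to whole numbers and tested with edgeR 4.0.16 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest) in R 4.3.3. A single fit of group means covered all 9 libraries, and 13462 genes passed the filter. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Correlations, distances and principal components used log2 CPM with a prior count of 2. A fold against a group with no counts was computed against 3 counts over the group and is given as at least that fold. This is a convention, and the exact 95% counting limits were lower. For ESC-derived against adult they were 1587, 1557, 447 and 425 in place of 1952, 1915, 550 and 523. For ESC-derived against fetal they were 459 and 100 in place of 565 and 124. Intervals of ratios are exact at 95%. Comparisons of single values used exact permutation tests. The 3 libraries of a group come from separate lines per the series description, and their numbers follow the order of deposition, so they pair nothing across groups. Pairs of libraries within a group differed by a chi-square of 62.0 to 160.1 per degree of freedom, so none was the same library sequenced again. This statistic cannot tell separate lines from repeat cultures of the same line.

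The procedure was tested on simulated data with 200 changed genes of the 13462. For ESC-derived against adult it recovered 13.4% of 2-fold, 70.1% of 4-fold and 84.8% of 8-fold changes with 4 false calls. For ESC-derived against fetal the shares were 16.4%, 70.1% and 87.9% with 3 false calls. For fetal against adult they were 13.4%, 83.6% and 87.9% with 6 false calls.

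Alternatives were RLE scaling, total counts alone, DESeq2 1.42.0, limma 3.58.1 with voom, no filter, a filter of 5 CPM in 3 libraries, a test for changes beyond 2-fold, fits of only the 6 libraries compared, passage as a covariate, and leaving out each library in turn. Further alternatives were added after seeing the data: thinning to the lowest total, leaving out genes with fractional counts, leaving out the 100 most abundant genes of each library, DESeq2 without adult replicate 1, and folds of the genes shown without each library in turn.

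The table does not pair its identifiers with gene names. In the RefSeq gene table used here, 0 rows carry an Ensembl identifier, so 0 identifiers were matched to a symbol and none is named. The 38 gene lists fixed beforehand, which covered tenocyte, pluripotency, antigen presentation and immune suppressive genes among others, were therefore not tested: 0 of the 38 could be run. The rule for named genes asked for a symbol, an adjusted p under 0.05, no overlap between groups and 10 CPM in the higher group, ranked by fold change. It was applied without the symbol to ESC-derived against adult, and the 2 highest and 2 lowest identifiers are shown. Restricting it to that comparison was decided after values had been seen. Identifiers shown for fetal against adult were likewise chosen after their values were seen. No coordinates are given.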

Results

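Messenger RNA was profiled in 9 cultures of horse tenocytes grown in 2D: 3 ESC-derived, 3 fetal and 3 adult lines. Library totals were 20292588 to 22569445 counts in ESC-derived, 20166692 to 23436766 in fetal and 21454277 to 23767643 in adult cultures (n = 3 each). At 10 counts or more, 12529 ± 151 genes were detected in ESC-derived, 12532 ± 49.8 in fetal and 12411 ± 241 in adult libraries (SD, n = 3 each). Genes are given by identifier because the table does not pair identifiers with names.

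The ESC-derived cultures stood apart from both kinds of primary tenocyte, and fetal and adult cultures lay among each other. Across genes, Pearson's r of log2 CPM was 0.956 to 0.974 between ESC-derived lines, 0.952 to 0.972 between fetal lines and 0.946 to 0.965 between adult lines. Between fetal and adult lines it was 0.927 to 0.973, and it fell to 0.577 to 0.603 for ESC-derived with fetal and 0.559 to 0.596 for ESC-derived with adult lines. Genes are not independent replicates, so these describe pairs of libraries. The root mean square log2 difference was 2.71 between ESC-derived and adult, 2.63 between ESC-derived and fetal, and 0.83 between fetal and adult libraries. Within groups it was 0.77, 0.75 and 0.87 for ESC-derived, fetal and adult. In the exact test over 10 splits, one-sided, the excess of between-group over within-group distance gave p = 0.1 for each ESC-derived comparison, the smallest this design allows. For fetal against adult it was 0.02, with exact p = 0.2.

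**Figure D1:**
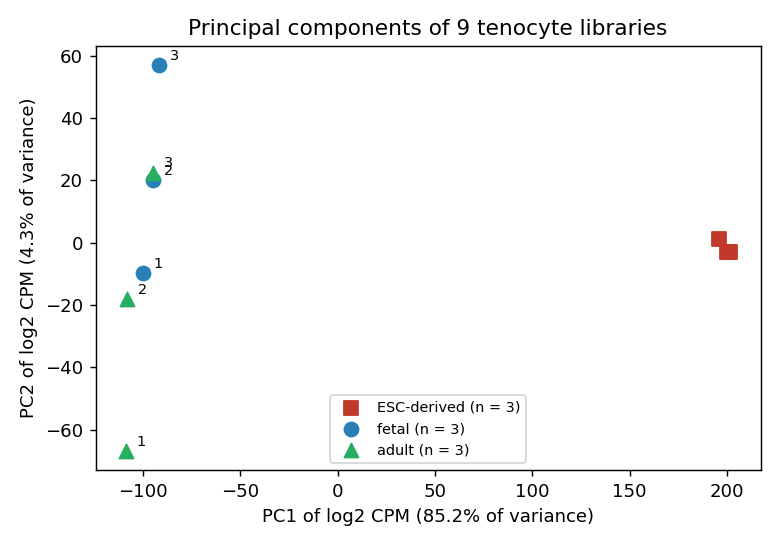
Principal components of log2 CPM for 9 libraries, with PC1 (85.2% of variance) on the horizontal axis and PC2 (4.3%) on the vertical axis; points are libraries, with replicate numbers beside the primary ones. The 3 ESC-derived libraries lie at one end of PC1 and the 6 primary libraries at the other. Along PC2 adult replicates 1 and 2 lie below the fetal points, and adult replicate 3 lies among them.

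Counts were spread over more genes in ESC-derived cultures. The 10 most abundant genes of a library held 10.1% ± 0.653 of counts in ESC-derived, 16.7% ± 1.86 in fetal and 17.4% ± 3.49 in adult libraries (SD, n = 3 each). The 100 most abundant held 27.3% ± 1.85, 38.7% ± 2.55 and 39.3% ± 3.89 (SD, n = 3 each). Both shares were lower in the 3 ESC-derived libraries than in every one of the 6 primary libraries (exact permutation test, two-sided, p = 0.0119 for each, the smallest possible, and 0.0278 after Benjamini-Hochberg adjustment over 7 library measures). The percentage of genes with a fractional count was higher in every ESC-derived library, 8.96% ± 0.167 (SD, n = 3), than in the primary ones at 6.79% to 7.67%, with the same exact permutation p of 0.0119 and 0.0278 after adjustment. The share of counts that these genes held overlapped, at 18.4% ± 1.57 in ESC-derived libraries (SD, n = 3) and 15.6% to 19.3% in primary ones. For that share the exact permutation p was 0.31, and 0.433 after adjustment. Fetal and adult shares of the 10 and 100 most abundant genes gave exact p = 0.8 and 0.9. Of their 100 most abundant genes, 39 to 46 were shared by an ESC-derived and a fetal library, 40 to 45 by an ESC-derived and an adult library, and 78 to 91 by a fetal and an adult library.

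**Figure D2:**
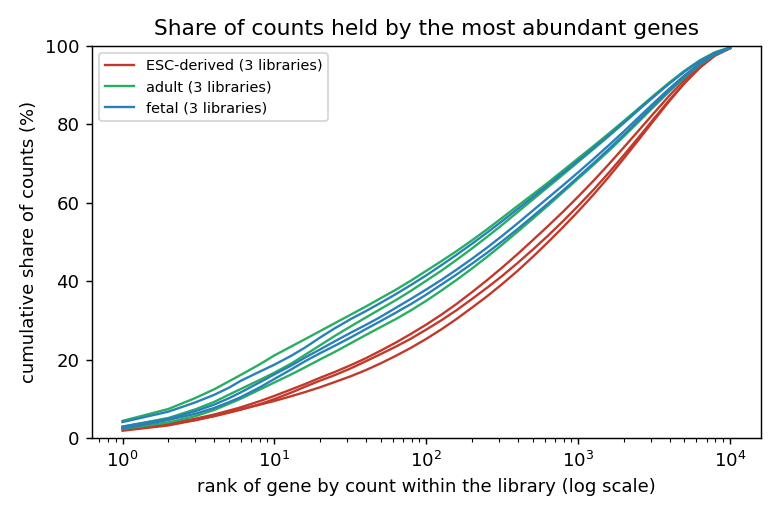
Cumulative share of counts (%) against the rank of genes by count within each library (log scale), 1 line per library and 3 libraries per group. At rank 100 the ESC-derived lines lie between 25.3% and 29.0%, below the primary lines at 35.1% to 42.7%.

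To ask how ESC-derived tenocytes differ from adult tenocytes, their libraries were compared gene by gene. Of 13462 genes tested, 7843 (58.3%) differed, 3804 higher and 4039 lower in ESC-derived cultures. Changes were large: the median absolute log2 fold change of called genes was 1.74, also with genes absent from a group placed at their bound, and 5772 genes changed at least 2-fold, 3542 at least 4-fold and 2006 at least 16-fold. Genes higher in ESC-derived cultures held 42.8% ± 0.696 of ESC-derived counts and 9.09% ± 1.61 of adult counts, whereas genes lower there held 21.5% ± 0.436 and 62.1% ± 3.31 (SD, n = 3 each). At 50 counts or more in each library of one group and 3 or fewer in each of the other, 233 genes were present in ESC-derived and not adult cultures, and 200 in adult and not ESC-derived cultures. ENSECAG00000022594 was at 94.5 ± 11.7 CPM in ESC-derived cultures and at 0 in adult ones (SD, n = 3), at least 1952-fold higher (edgeR adjusted p = 4.99e-06). ENSECAG00000011388 was at 92.2 ± 29.2 CPM against 0, at least 1915-fold higher (edgeR adjusted p = 1.09e-05). ENSECAG00000029663 was at 0 in ESC-derived and 22.2 ± 3.59 CPM in adult cultures, at least 550-fold lower (edgeR adjusted p = 3.10e-06). ENSECAG00000007097 was at 0 against 20.9 ± 16.6 CPM, at least 523-fold lower (edgeR adjusted p = 0.000655), with 38.8, 6.04 and 17.9 CPM in adult replicates 1, 2 and 3. These bounds are set against 3 counts over the group by convention. The exact 95% counting limits were lower, at 1587, 1557, 447 and 425 in the order of these genes. Leaving out 1 library at a time, in the same order, the bounds ran from 1266 to 2059, 1241 to 2227, 362 to 596 and 305 to 696. The first 2 were lowest without adult replicate 3, the next without ESC-derived replicate 1 and the last without adult replicate 1. For all but the last, the library left out held 0 counts of the gene. Those bounds fell because 3 counts were set against less depth. The libraries of the groups did not overlap for 66.6% of tested genes, where chance gives 10%. With total counts in place of TMM scaling, the split of calls moved from 48.5% to 61.9% higher in ESC-derived cultures (4895 higher, 3018 lower), so the balance of directions depends on the scaling. When only changes beyond 2-fold were tested, 4027 genes passed.

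**Figure D3:**
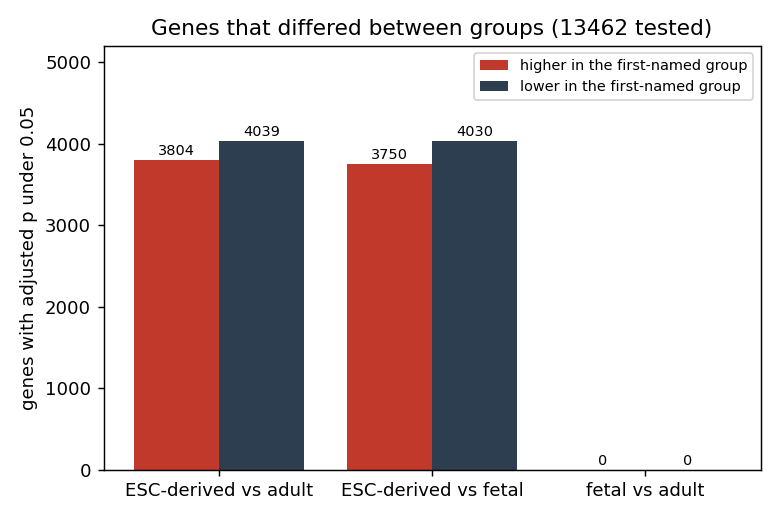
Number of genes with an edgeR adjusted p under 0.05 for each comparison, split by direction, of 13462 tested with 3 libraries per group. Both ESC-derived comparisons have at least 3750 genes in each direction under TMM scaling, and fetal against adult has 0; with total counts alone the ESC-derived splits shift to 61.9% and 59.8% higher.

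The comparison with fetal tenocytes gave a similar number of genes. In ESC-derived cultures 3750 genes were higher and 4030 lower than in fetal ones, 7780 (57.8%) of those tested, with a median absolute log2 fold change of 1.71, also with absent genes at their bound. Of these, 5681 changed at least 2-fold, 3461 at least 4-fold and 1949 at least 16-fold. Genes higher in ESC-derived cultures held 42.7% ± 0.623 of ESC-derived and 9.37% ± 0.701 of fetal counts, and genes lower there held 21.3% ± 0.157 and 60.4% ± 3.29 (SD, n = 3 each). At the same limits of 50 and 3 counts, 167 genes were present in ESC-derived and not fetal cultures, and 221 in fetal and not ESC-derived cultures. ENSECAG00000022594 was at 0.311 ± 0.195 CPM in fetal cultures, so that its log2 fold change was 8.22 ± 0.44 (SE, edgeR adjusted p = 8.99e-06). ENSECAG00000011388 had 2 counts over the fetal libraries, both in fetal replicate 1, a ratio of 2835 (95% counting interval 784 to 23412). Without that library it was at least 1245-fold higher, and without fetal replicate 3 the ratio was 1873. ENSECAG00000029663 and ENSECAG00000007097 were at 22.8 ± 5.27 and 5.02 ± 3.11 CPM in fetal cultures, at least 565-fold and 124-fold above the ESC-derived ones by the same convention (exact 95% counting limits 459 and 100). With 1 library left out at a time these bounds ran from 373 to 636 and from 81.6 to 169, lowest without ESC-derived replicate 1. That library held 0 counts of either gene, so the bounds fell there because 3 counts were set against less depth. The libraries did not overlap for 67.4% of genes, where chance gives 10%. Total counts alone moved the split of calls from 48.2% to 59.8% higher (4577 higher, 3078 lower), and 3974 genes passed when only changes beyond 2-fold were tested.

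The comparisons of ESC-derived cultures with adult and with fetal ones called many genes in common. In both, 3419 genes were higher and 3702 lower in ESC-derived cultures, 7121 in all and 90.8% and 91.5% of the calls, and 0 genes were called in opposite directions. Independent lists of these sizes would share 1060 higher and 1209 lower genes, and 20 simulations of unchanged libraries shared at most 0. Simulated libraries held no effects, so that 0 does not measure the overlap that shared libraries add to real effects. The fold changes correlated at r = 0.973 across genes, against 0.484 in the simulations, with a covariance of 8.88 against 0.134. The 3 ESC-derived libraries serve both comparisons and cannot be divided into parts of at least 2, so part of the excess may come from the shared libraries. At 50 counts or more against 3 or fewer, 141 genes were present in every ESC-derived and no primary library, and 173 in every primary and no ESC-derived library. Of the 208 genes among the 100 most abundant of any library, 66 were higher and 97 lower in both comparisons, and 38 were called in neither. A further group of 3891 genes had 50 counts or more in all 9 libraries and was called in neither comparison; it held 31.9% ± 0.319 of ESC-derived, 27% ± 2.34 of fetal and 25.6% ± 1.58 of adult counts (SD, n = 3 each).

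**Figure D4:**
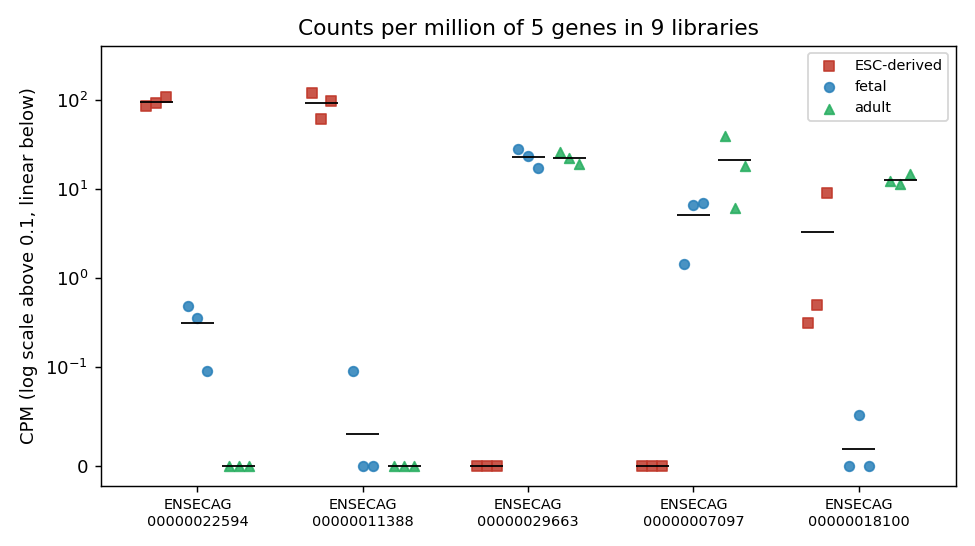
Normalised abundance (CPM) of 5 genes in 9 libraries (log scale above 0.1, linear below); points are libraries, 3 per group, and bars are group means. The 2 genes at the left are at 61.3 CPM or more in each ESC-derived library and below 0.5 in each primary one, the next 2 are at 0 in the ESC-derived libraries, and ENSECAG00000018100 is at 11.3 CPM or more in the adult libraries and below 0.1 in the fetal ones.

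Fetal and adult tenocytes differed far less. By edgeR 0 of 13462 genes differed, with 581 (4.32%) at an unadjusted p under 0.05 and a lowest adjusted p of 0.498. The unadjusted count rose to 966 of 13825 without fetal replicate 1 and 953 of 13833 without adult replicate 3. It fell to 432 of 13817 without adult replicate 1 and 426 of 13822 without fetal replicate 3. The median absolute log2 fold change over all tested genes was 0.17, against 0.91 and 0.89 in the comparisons of ESC-derived cultures with adult and fetal ones. At 50 counts or more against 3 or fewer, 0 genes were present in fetal and not adult cultures, and 1 in adult and not fetal cultures. That gene, ENSECAG00000018100, chosen after its values were seen, was at 12.7 ± 1.60 CPM in adult and 0.0170 ± 0.0295 CPM in fetal cultures (SD, n = 3), with 790 counts against 1, a ratio of 780 (95% counting interval 140 to 30833). The 1 count was in fetal replicate 2, without which the gene was at least 177-fold higher in adult cultures; without fetal replicate 1 or 3 the ratio was 514 or 515. Its log2 fold change of -9.17 ± 1.74 (SE) had an edgeR adjusted p of 0.552, and it ranged from 0.315 to 9.01 CPM between ESC-derived lines. Libraries of the groups did not overlap for 7.13% of genes, where chance gives 10%. The count depended on the tool: limma-voom called 0 genes (529 at an unadjusted p under 0.05) and DESeq2 called 52, 37 higher and 15 lower in fetal cultures (744 at an unadjusted p under 0.05). In a fit of the 6 fetal and adult libraries alone, ENSECAG00000018100 was the 1 gene called (edgeR adjusted p = 0.0113).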

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

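Alternatives by thinning, by leaving out genes with fractional counts or the most abundant genes, by DESeq2 without adult replicate 1, and folds of single genes without each library were chosen after the result was seen; the others were chosen before the data were examined. Counts of calls stayed within 1.5 times of 7843 for ESC-derived against adult, 7780 for ESC-derived against fetal and 7121 for both under the alternatives run on these comparisons, except the test for changes beyond 2-fold, which gave 4027, 3974 and 3649 because it asks for a larger change. Leaving out each library in turn gave 6785 to 8040, 6683 to 8121 and 6147 to 7156 genes. Passage as a covariate and DESeq2 without adult replicate 1 were run for fetal against adult only. Total counts alone turned the split from more lower to more higher calls, 4895 higher and 3018 lower against adult and 4577 and 3078 against fetal cultures. They shifted the median log2 fold change by 0.32 and 0.27 in the ESC-derived comparisons with adult and fetal cultures. Of their 7913 and 7655 calls, 6822 and 6828 were also called under TMM scaling. Smaller turns came in the 6-library fits (3641 higher and 3633 lower against adult, 3866 and 3748 against fetal). They also came without adult replicate 3 (4016 and 3919, 4126 and 3995) and, against fetal, without ESC-derived replicate 3 (3546 and 3515). For fetal against adult, edgeR gave 0 genes under RLE scaling, total counts, no filter and the stricter filter, and limma-voom 0, but DESeq2 gave 52 and DESeq2 without adult replicate 1 gave 28; the cause was not tested. Of the 52, 51 were tested by edgeR and all 51 had an unadjusted p under 0.05 and the same direction there. Leaving out libraries gave 0 to 1 genes: 1 without ESC-derived replicate 3 (ENSECAG00000018100, edgeR adjusted p = 0.00575) and 1 without fetal replicate 3 (ENSECAG00000014086, log2 fold change 3.25, edgeR adjusted p = 0.0198). The 6 libraries alone and passage as a covariate each gave 1, ENSECAG00000018100 (edgeR adjusted p = 0.0113 and 0.0369); its adjusted p was 1.13e-05 by DESeq2 and ranged up to 1 over the alternatives. The direction of the genes shown did not change in any alternative that tested them; ENSECAG00000022594, ENSECAG00000029663 and ENSECAG00000018100 hold fractional counts and were not in the fit without such genes, and ENSECAG00000018100 was not in the 6-library fit of ESC-derived against fetal. The gene list tests were not run, and pseudocounts did not apply to counts. Totals differed little, and depth limits mainly genes near 0 counts, whose folds are bounds at 0 counts and ratios with wide counting intervals at 1 to 3.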

Other observations

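The tests over splits of 6 libraries and of reads carried over were chosen only after the result was seen, as were the alternatives by thinning, by leaving out genes and by DESeq2 without adult replicate 1. Leaving out each library was planned, but its use as a test of a divergent adult line was chosen after the result. Genes present in single lines set adult replicate 1 apart. At 50 counts or more in one library and 3 or fewer in the other 8, it held 34 genes, where the next library held 4. Their counts ran from 50 to 1585 with a median of 170, 8 of them were at 0 in every other library, and together they held 0.0471% of its counts. With lower limits of 20 and 100 counts the number was 53 and 25. At 1 CPM or more, 80 genes were at least 16-fold above each of the other 5 primary libraries in adult replicate 1, against 0 to 3 in the others. Conversely, 10 genes with 50 counts or more in the other 8 libraries were at 3 or fewer in ESC-derived replicate 3.

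Between ESC-derived and adult cultures 7843 of 13462 genes were called. Depth argues little for this, since thinning to the lowest total left 7802 calls, and leaving out the 100 most abundant genes of each library left 7642. More genes held a fractional count in ESC-derived libraries (8.96% against 6.79% to 7.67%). The share of counts held by such genes overlapped (16.8% to 19.9% against 15.6% to 19.3%). Reads shared between genes do not account for the calls, since 57.56% of genes without a fractional count were called, against 58.3% of all. In fits of 6 libraries, 10 splits are too few for a share under 0.05; the real split called 7274 genes against adult and 7614 against fetal cultures, 1 split in each case, and the highest other 0. For the 7121 genes called in both comparisons, 1 of 100 regroupings of the 9 libraries, the real one, gave as many and the highest other gave 0. Chance in the grouping is thus unlikely to give so many, at the limit of 1 in 100. The regroupings do not show how much of the overlap comes from the shared ESC-derived libraries. Origin, passage, medium, serum, TGF-β3 and earlier culture on mouse feeder cells cannot be told apart because the design changes them together.

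The low count between fetal and adult cultures, 0 by edgeR, 0 by limma-voom and 52 by DESeq2, has more than 1 open explanation. Without adult replicate 1 edgeR called 0 genes and DESeq2 28, and genes at an unadjusted edgeR p under 0.05 fell from 581 to 432. They also fell without fetal replicates 2 and 3, to 508 and 426. They rose to 966, 953 and 747 without fetal replicate 1, adult replicate 3 and adult replicate 2. EdgeR called 0 genes in each case, except 1 without fetal replicate 3. The count moved both ways, so it does not decide whether a divergent adult replicate 1 widened the spread. Too few libraries may contribute: of 1022 changes of 4- to 8-fold measured between ESC-derived and adult cultures, 91.6% were called among many others, but 13% had a p below 0.05 divided by the number of genes, the limit an isolated change must pass. The simulation recovered 83.6% of 4-fold changes, but it drew libraries from the fitted dispersions and many genes changed together, so meeting the bound of 20% set for it excludes nothing. The 10 splits of the 6 libraries are too few for a share under 0.05; the real split called 1 gene and the highest other 2, as 2 splits called at least as many, and similarity of the lines themselves stays open and untested.

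For the 34 genes present in adult replicate 1 alone, depth is argued against, since 33 remained after thinning to the lowest total. Reads shared with a similar gene would leave fractional counts, and 11.8% of the 34 genes held one. Reads carried over from an ESC-derived library could not be tested on the 34 genes, whose selection fixes the outcome. As selected, the 34 held 3 or fewer counts in each other library, against 50 or more in adult replicate 1. These low counts are the selection rule itself and no test, although a library with 3 or fewer counts could hardly supply 50 or more. Sources outside these libraries were not examined. Of the other 46 of the 80 genes far above the other primary libraries, 2 (4.35%) were higher in an ESC-derived library. That argues against reads carried over from an ESC-derived library for these 46 as a set, and does not bear on other sources. RNA from other cells or a variant of that line may remain as candidate explanations; neither was tested, because the identifiers were not paired with names, and no biological explanation was tested.

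A hypothesis set before its result was seen was that fetal lines lie towards the ESC-derived lines. The correlation across genes of the fetal minus adult difference with the ESC-derived minus primary difference was 0.138, and another of the 20 ordered splits of the 6 primary libraries gave 0.161. The share of splits as high was 3 of 20 (exact permutation test, one-sided, p = 0.15), so no such shift was shown. A higher split had been set beforehand to count against the hypothesis, and that outcome occurred. The gap between these values was 0.0229, and the SD over the 20 splits was 0.0972. That SD was looked at after the values were seen and is the spread over splits, not the error of the gap. It therefore does not set the outcome aside. With so few libraries, absence of a shift was not shown either. The distance to the ESC-derived libraries was 2.63 ± 0.03 for fetal and 2.71 ± 0.08 for adult libraries (log2 units, SD, n = 3 each; exact permutation test, two-sided, p = 0.2).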
